A study of Mus musculus with 8 samples.

How the data were processed

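Total RNA from the cortex of 8 mice of the CD1 strain at postnatal day 10 was measured on Affymetrix mouse exon arrays, with 1 array per mouse. The labels put 4 mice in the wild type group and 4 in the Nova2 knockout (Nova2 KO) group. An exon array carries several short probe sets along each gene, so that the signal of single exons can be set against the signal of the gene. Per the labels' protocols, RNA was extracted with Trizol and labelled with the Affymetrix sense-strand assay for whole transcripts.

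The deposited values numbered 1 per array for each of 391597 probe sets, on a log2 scale. Per the submitters' processing notes, the values were made with PLIER, a model-based summary of the probes of a probe set; its version was not given. Background correction, normalization between arrays, the genome build and the rule by which these probe sets were chosen were not given in the sources used here. The smallest value of every array lay at about 4, which an offset of 16 added before the logarithm would give. Array medians ran from 7.02 (wild type 4) to 7.37 (Nova2 KO 2), a difference of 0.352 log2 or 1.28-fold, so the values were taken as normalized by the authors and left as deposited. Values at the floor, within 0.01 log2 of 4, made up 0.991% to 3.34% of an array, with the highest shares in wild type 4 (3.34%) and Nova2 KO 4 (2.20%). Spearman correlations between arrays ranged from 0.935 to 0.976. Arrays have no read depth, and their number limits the precision.

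Probe sets were named through the platform annotation: 228454 named 1 gene, 3443 named several genes and 159700 were unnamed here. Of 13017 symbols on probe sets with 1 gene, 10783 were current in the mouse gene table of assembly GRCm38.p6, 2203 were updated through a synonym and 31 were left as given. The build behind the probe sets was not given in the sources used here, so that table served only for names and for which genes neighbour Nova2, and no coordinates are printed. Which exon a probe set covers was not analysed here.

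The computations used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Probe sets were kept where the mean over the 8 arrays exceeded the 25th percentile of all probe sets (5.86 log2), which left 293697, of which 198965 named 1 gene. The gene value of an array was the median log2 value over the kept probe sets that named that gene alone, for genes with 3 or more of them. The splicing index was the log2 value of a probe set minus the gene value of the same array, for genes with 5 or more such probe sets. It rises when a probe set gains signal relative to its gene, and a gene value that moves for another reason shifts it as well. Each measure was tested with lmFit and eBayes of limma as Nova2 KO minus wild type, two-sided, with Benjamini-Hochberg adjustment at 0.05. Genes were called for exon usage from the Simes p over their probe sets, adjusted in the same way. In exon usage, 307 probe sets had an index without variance, since they set the gene's median themselves.

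The following choices were made before the data were examined: the tests, 27 gene lists, the other settings to be tried and the rule for naming genes. The rule named Nova2 and Nova1, then the 10 rising and the 10 falling genes with the largest log2 change among those past the threshold whose 4 Nova2 KO values all lay on one side of the 4 wild type values. The same rule chose 10 rising and 10 falling probe sets for exon usage, 1 per gene. It added up to 4 members per list with the lowest p, every gene past the threshold of the list of genes with a Nova-dependent exon, and genes near Nova2 past the threshold. Genes outside the rule are named as such. The lists covered splicing regulators, genes with a known Nova-dependent exon or 3-prime end, presynaptic and postsynaptic genes, GIRK channels and GABA-B receptors, the reelin pathway, axon guidance, immediate early genes, p53 targets, the cell cycle, markers of cortical layers, interneurons, glia, vessels, meninges, choroid plexus, neighbouring brain regions and blood, sex-linked genes, and genes near Nova2.

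For each list, members past the threshold were counted over all genes and adjusted over the list alone. The 20 expression lists with 3 or more measured genes were tested with camera of limma, which compares a list with all other genes, with a preset correlation of 0.01 and with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance. The mixed test of fry, which asks for changes in either direction, was read after the values were seen and adjusted over all 23 lists with 3 or more measured genes. The count of called genes on the Nova-dependent exon list was set against 10000 random lists matched on the number of probe sets and mean expression. Shares of called genes within 10 Mb of Nova2 were compared with Fisher's exact test. Per-array scores were compared with exact permutation tests over the 70 assignments of 4 among 8 arrays, which can give no two-sided p under 0.0286.

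Recovery by limma was tested on simulated data. Known changes were added to independent normal noise with the mean and spread of each probe set, gene value or splicing index on these arrays. The filter, the forming of gene values and indices, and structure shared between arrays were not simulated, so the shares may differ for the real data. At the gene level (11992 genes), 51.5% of genes changed by 0.5 log2, 92.4% of those changed by 1 log2 and 100% of those changed by 2 log2 were recovered, and 12 of 174 calls were false. In exon usage (194707 probe sets), the recovered shares were 1.47%, 54.5% and 90.9% for the same sizes, with 4 false calls of 101. Single probe sets (293697 tested) were recovered in 0%, 18.2% and 71.2%, with 1 false call of 60.

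The analyses were repeated with other settings, fixed in advance: quantile normalization, median centring, no filter or a filter at the 50th percentile, the replicate number of the titles as a block, eBayes with trend and robust options, the Xist value as a covariate, the mean over probe sets, other minimum numbers of probe sets, diffSplice of limma, genes above the median only, leaving out the genes near Nova2 and leaving out each array in turn. The array median as a covariate, leaving out both arrays numbered 4, and offsets of 1 and 64 in place of 16 were added after the data were seen. The planned offsets applied only to a table of linear values, and this table was on a log2 scale. Probe sets naming several genes or none entered only the test of single probe sets.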

Results

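Nova2 is a neuronal RNA-binding protein that regulates alternative splicing, and its knockout was compared with wild type in the cortex of CD1 mice at postnatal day 10. The comparison asks which transcripts and which exons depend on Nova2 at this age. Each group held 4 mice with 1 exon array each, and 391597 probe sets were read on every array. Xist, the RNA of the inactive X chromosome, was high (10.2 to 11.0 log2) on wild type arrays 1 and 4 and Nova2 KO arrays 2 and 4. On the other 4 arrays it lay between 4.59 and 5.24 log2, and the Y-linked gene Eif2s3y lay between 8.996 and 9.43 log2. Both groups thus held 2 arrays of each kind.

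Nova2 itself was examined first, as a check of the labels. Probe set 5294108 of Nova2 fell by 1.82 log2 (SE 0.22, n = 4 per group) in Nova2 KO, from 8.68 ± 0.14 to 6.86 ± 0.45 (mean ± SD), with an adjusted p of 0.000294 over the 16 Nova2 probe sets (limma). The 4 Nova2 KO arrays lay between 6.28 and 7.26 log2 and the 4 wild type arrays between 8.53 and 8.87 log2. Probe set 4414499 rose by 0.70 log2 (SE 0.13, adjusted p = 0.00462 over the 16). The other 14 Nova2 probe sets did not pass (for 1 of them, 5489900, Nova2 KO 3 stood apart), and the gene value differed by -0.016 log2 (SE 0.11, adjusted p = 0.975). The part of Nova2 that was deleted is not given in the sources used here, so probe sets outside it check nothing. Among the kept probe sets as a whole, 5294108 had an adjusted p of 0.0786. Nova1, the paralog of Nova2, differed by 0.38 log2 (SE 0.11, limma adjusted p = 0.251), with all 4 Nova2 KO values above all 4 wild type values.

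**Figure D1:**
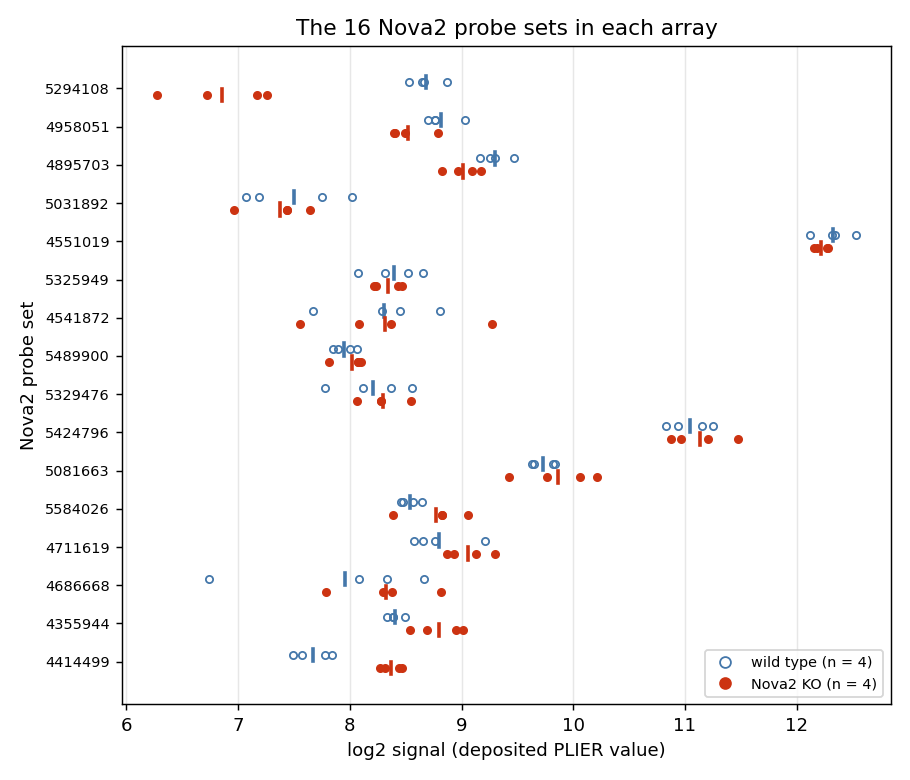
Log2 signal (x axis) of the 16 Nova2 probe sets (y axis) on each of the 4 wild type (open blue) and 4 Nova2 KO (filled red) arrays, with vertical bars at the group means. Probe set 5294108 lay between 8.53 and 8.87 in wild type and between 6.28 and 7.26 in Nova2 KO, and the groups overlapped for most of the others.

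At the gene level, Scn9a, which encodes the voltage-gated sodium channel Nav1.7, rose by 1.26 log2 or 2.40-fold in Nova2 KO (SE 0.14, n = 4 per group, limma adjusted p = 0.0038). Dcx, a microtubule-binding protein of migrating and immature neurons, rose by 0.81 log2 (SE 0.11, adjusted p = 0.0133). The call for Dcx was lost in 1 of 14 other settings, the mean over probe sets (0.60 log2, limma adjusted p = 0.094). Gpr45, an orphan G protein-coupled receptor, fell by 1.46 log2 (SE 0.11, adjusted p = 7.81e-05), and wild type was 2.75-fold above Nova2 KO. Gene values were low for Scn9a in wild type (6.53 log2) and for Gpr45 in Nova2 KO (6.26 log2), so these sizes are less certain. Itpr1, the inositol trisphosphate receptor that releases calcium from the endoplasmic reticulum, fell by 1.12 log2 (SE 0.13, adjusted p = 0.00574).

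In all, 25 of 11992 genes passed the threshold, 11 higher and 14 lower in Nova2 KO, and 1389 had an unadjusted p under 0.05. The other rising genes were Atg4a (1.07 log2, SE 0.18), a protease of the autophagy pathway; S100a10 (0.89 log2, SE 0.11), the binding partner of annexin A2; and Snrpe (0.80 log2, SE 0.11), a core protein of spliceosomal ribonucleoproteins. The DNA damage kinase gene Atm rose by 0.76 log2 (SE 0.11), and the adaptor gene Sla by 0.66 log2 (SE 0.10). Smaller rises were those of Cep112, which encodes a centrosomal protein (0.63 log2, SE 0.098), Map4, which encodes a microtubule-associated protein (0.61 log2, SE 0.093), and the zinc finger gene Zfp110 (0.54 log2, SE 0.095). Calls were lost in 9 of 13 other settings for Zfp110, in 5 of 14 for Cep112 and in 4 of 14 for Map4. They were lost in 3 of 14 for Snrpe and in 3 of 13 for Atg4a. Some sizes depended on how probe sets were filtered or summarised. With the filter at the 50th percentile, Cep112 was at 0.25, Zfp110 at 0.26 and Map4 at 0.47 log2, without a call. Without a filter, Snrpe was at 0.31 log2 (limma adjusted p = 0.537) and S100a10 at 0.60 log2, without a call. With the mean over probe sets, Snrpe was at 0.54, Map4 at 0.39 and Zfp110 at 0.26 log2, again without a call.

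The falling genes included a pair of bicarbonate transporter genes. Slc4a3, an anion exchanger, fell by 1.01 log2 (SE 0.12) and Slc4a10, a sodium-coupled bicarbonate transporter of neurons, fell by 0.83 log2 (SE 0.10). The kinase gene Lmtk3 fell by 1.04 log2 (SE 0.14) and Dzip1, which encodes a protein of the ciliary base, by 0.88 log2 (SE 0.14). The myelin genes Mal and Mog fell by 1.03 log2 (SE 0.16) and by 0.77 log2 (SE 0.13), with calls lost in 4 and 5 of 14 other settings. Mal was at -0.56 log2 with the mean over probe sets (limma adjusted p = 0.115). Lynx1, which encodes a modulator of nicotinic acetylcholine receptors, fell by 0.69 log2 (SE 0.097), and Rasgrf1, a Ras exchange factor, fell by 0.66 log2 (SE 0.11). Named after their values were seen, the remaining 5 were Dync1i1, which rose by 0.52 log2, and Gpr153 (-0.66 log2), Tmcc2 (-0.59 log2), Hpcal4 (-0.59 log2) and Srr (-0.55 log2), which were lower.

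Most probe sets of a called gene lay in the direction of its change. For Itpr1, 69 of 71 probe sets lay in the direction of the gene, for Atm 69 of 70, for Slc4a10 30 of 30, for Lmtk3 23 of 23 and for Dcx 16 of 16, against 27 of 33 for Map4, 9 of 12 for Zfp110, 8 of 10 for Gpr153 and 3 of 4 for Gpr45. Scn9a differed, with 23 of 27 probe sets higher by 0.27 to 1.80 log2, while the 4 brightest (9.03 to 11.34 log2 in wild type) differed by -0.31 to -0.031 log2. The 23 were dim, at 5.23 to 7.47 log2 in wild type. Those under the filter value of 5.86 log2 in wild type were kept through their higher Nova2 KO signal. For Atg4a and Itpr1, wild type array 4 stood apart from the other 3 wild type arrays, as did wild type array 2 for Map4 and Slc4a3. Leaving out any of the 8 arrays lowered the number of genes past the threshold, to between 6 (without wild type 1) and 16 (without wild type 4), and leaving out both arrays numbered 4 gave 12. Median centring of the arrays gave 13 genes, and the array median as a covariate gave 54. The replicate number of the titles as a block gave 80.

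**Figure D2:**
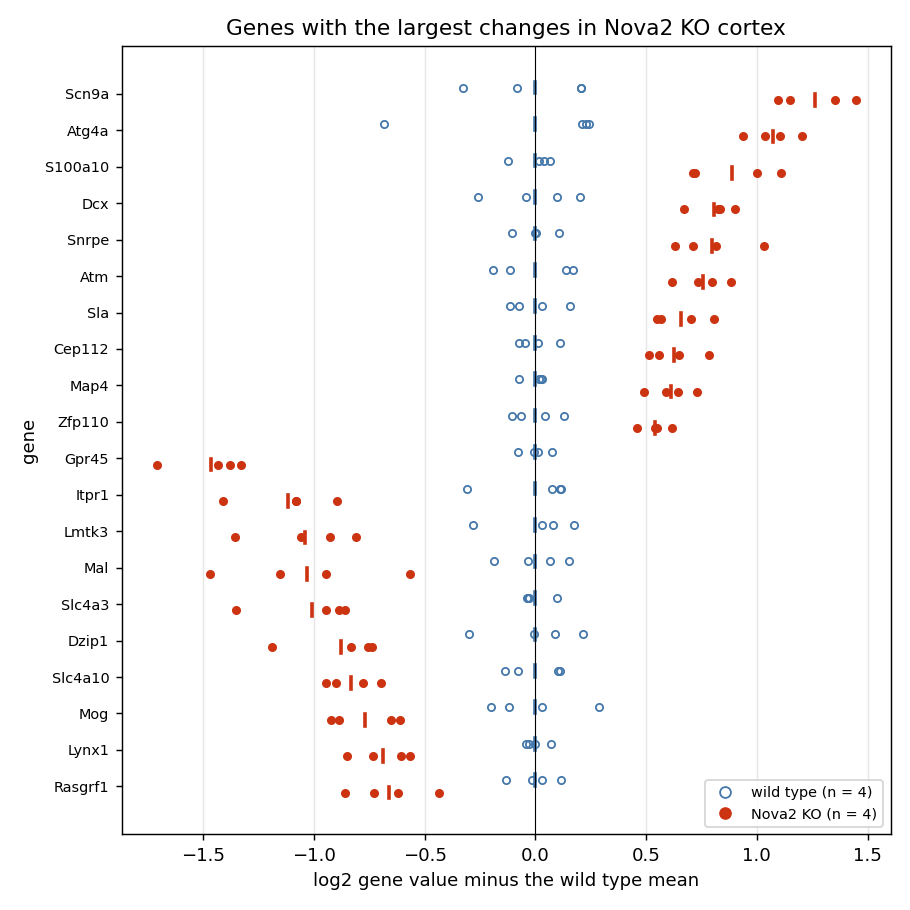
Gene values on each array minus the wild type mean of the gene (x axis, log2) for the 20 named genes (y axis), with open blue points for wild type, filled red points for Nova2 KO and vertical bars at the group means. The Nova2 KO points of each gene lay all above or all below the 4 wild type points, from Scn9a (1.26 log2 higher) to Gpr45 (-1.46 log2).

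Exon usage asked whether single probe sets changed relative to their gene, which is where a splicing regulator would act. A probe set of Chl1, a neural cell adhesion molecule of the L1 family, rose by 2.89 log2 relative to the gene in Nova2 KO (7.39-fold, SE 0.20, n = 4 per group, limma adjusted p = 0.00484). A probe set of Ank3, which encodes ankyrin-G of the axon initial segment, rose by 2.75 log2 (6.71-fold, SE 0.14, adjusted p = 0.00361), and 1 of Gphn, the scaffold gephyrin of inhibitory synapses, by 2.45 log2 (5.47-fold, SE 0.14, adjusted p = 0.00374). A probe set of Tln2, which encodes the adhesion linker talin-2, fell by 2.91 log2 (SE 0.30, adjusted p = 0.0451), a call that was lost in 6 of 16 other settings. Since its Nova2 KO signal (5.97 log2) was near the lowest signal kept, the size is better read as a lower bound, and offset 1 gave -3.30 log2.

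In total, 26 of 195014 probe sets passed, 11 higher and 15 lower relative to their gene, and 13178 had an unadjusted p under 0.05. They lay in 24 genes, and 18 of 11187 genes passed by the Simes p (936 at an unadjusted p under 0.05). Among genes of membrane proteases without catalytic activity, Adam22 rose by 2.80 log2 (SE 0.22) and Adam11 by 2.62 log2 (SE 0.19). Probe sets of the glutamate receptor genes Grik2 (2.49 log2, SE 0.16), Gria3 (1.67 log2, SE 0.17) and Grin1 (1.29 log2, SE 0.085) rose, and the call for Gria3 was lost in 6 of 15 other settings. Wild type signal was low for Grik2 (5.57 log2), Gria3 (6.07 log2) and Adam22 (6.13 log2), so these sizes are better read as lower bounds. A probe set of Ank2, which encodes ankyrin-B, rose by 1.68 log2 (SE 0.10) and 1 of Cyp2d9, a cytochrome P450 gene, by 1.22 log2 (SE 0.11). The call for Cyp2d9 was lost in 5 of 13 other settings.

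Among the falling probe sets, the index fell by 1.33 log2 in Sptan1 (SE 0.090), which encodes alpha-II spectrin, by 1.33 log2 in Map7d2 (SE 0.13), a microtubule-binding protein, and by 1.18 log2 in Cltc (SE 0.11), the clathrin heavy chain. It fell by 1.27 log2 in the adhesion gene Nrcam (SE 0.12), by 1.34 log2 in Abi3bp (SE 0.13; call lost in 6 of 15 other settings) and by 1.68 log2 in Ociad1 (SE 0.13). Probe sets of Sphkap, a kinase A anchoring protein, and Kcnma1, the BK potassium channel, fell by 1.65 log2 (SE 0.14) and by 1.15 log2 (SE 0.098), with wild type 4 apart from its group for Kcnma1. A probe set of Aplp2, from the amyloid precursor family, fell by 1.15 log2 (SE 0.079). Calls were lost in 5 of 16 other settings for Cltc, in 4 of 16 for Map7d2 and in 3 of 16 for Nrcam and for Kcnma1. In Scn9a the index of the brightest probe set fell by 1.57 log2 (SE 0.11), although its own signal differed by only -0.31 log2, because the gene value was higher in Nova2 KO. Outside the rule, and named after their values were seen, were rising Ncdn (1.10 log2) and falling Dclk1 (-1.01 log2) and Dbndd2 (-0.87 log2), a further Scn9a probe set (-1.46 log2) and a further Grin1 probe set (-0.93 log2).

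The signals themselves moved in the same way. On the signal scale, without division by the gene, the Chl1 probe set was at 6.84 ± 0.22 log2 (SD, n = 4) in wild type and 9.97 ± 0.34 log2 in Nova2 KO, and the Tln2 probe set at 9.19 ± 0.16 and 5.97 ± 0.61 log2. In the test of single probe sets, 20 of 293697 passed, 10 higher and 10 lower (19610 at an unadjusted p under 0.05), and 12 of the 20 were also called in exon usage. Of these 20, 14 named 1 gene, among them Chl1, Ank3, Gphn, Tln2 and Slc4a10, and 6 were unnamed. The rising unnamed probe sets with the largest change were 4351220 (2.49 log2) and 4344889 (1.96 log2), and the falling ones were 5182010 (-1.66 log2) and 5608399 (-1.50 log2). Leaving out single arrays gave 10 (without wild type 3) to 16 (without Nova2 KO 1) exon usage probe sets, 0 (without wild type 1) to 13 (without Nova2 KO 2) genes by Simes, and 0 (without wild type 1) to 9 (without Nova2 KO 4) single probe sets. Quantile normalization gave 29 higher and 57 lower single probe sets, and median centring 32 higher and 53 lower. Without both arrays numbered 4, the exon usage count was 2, and it was 506 with diffSplice, which pools the spread over the exons of a gene. With the replicate number of the titles as a block the exon usage count was 4, and 3 genes passed by Simes.

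**Figure D3:**
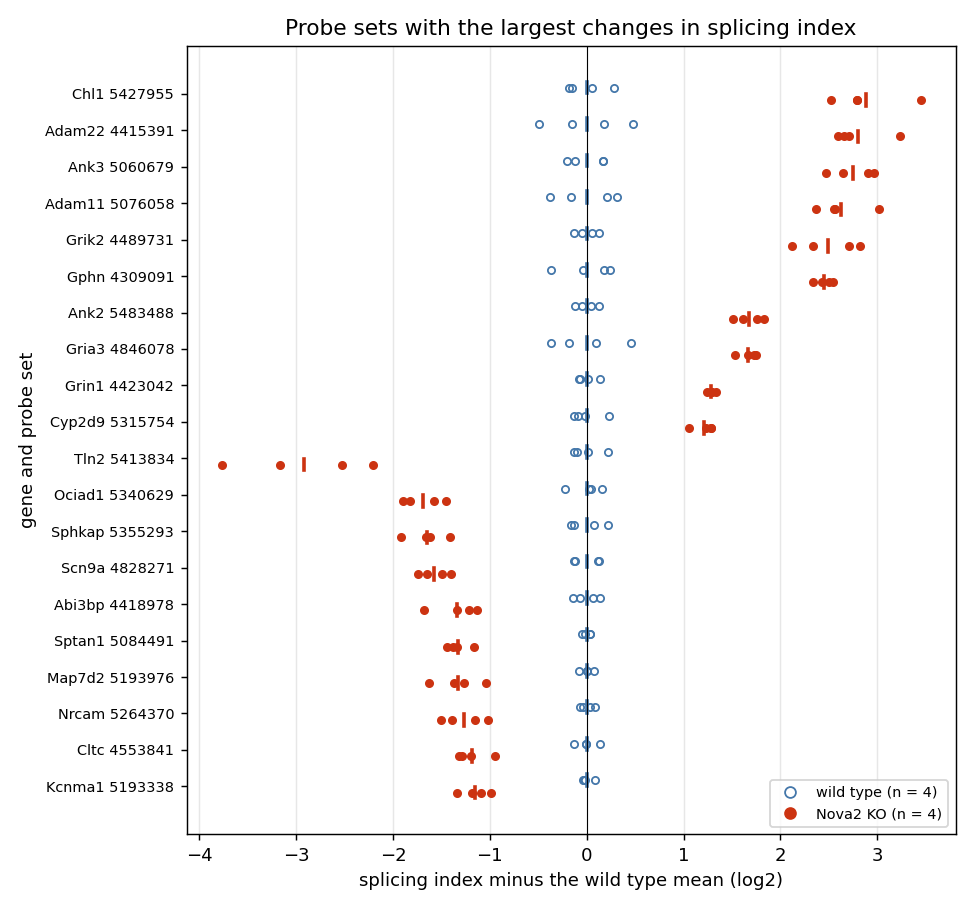
Splicing index on each array minus its wild type mean (x axis, log2) for the 20 named probe sets, labelled by gene (y axis), with open blue points for wild type, filled red points for Nova2 KO and vertical bars at the group means. Chl1 (2.89 log2 higher) and Tln2 (-2.91 log2, a bound since its Nova2 KO signal was low) lie at the ends, and the 4 arrays of each group did not overlap for any probe set shown.

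Genes with a known Nova-dependent exon were more often called in exon usage than other genes. Of 34 listed genes, 30 were measured and 6 passed: Gphn, Ank3 and Chl1 rose, and Aplp2, Sptan1 and Kcnma1 fell in their leading probe set. Adjusted over the list alone, 16 passed, among them Nrcam, Neo1 and Rap1gap. Map4 was also among the 16, but its probe set differed by only -0.065 log2 in signal, and its index fell by 0.68 log2 because the gene value rose. Matched random lists held 0.457 called genes on average and at most 5, and the one-sided permutation p was 0.0001, the smallest that 10000 lists can give. The list comes from earlier work on Nova proteins, in part on brains without Nova2, and is not independent evidence. Without wild type 1, wild type 3 or Nova2 KO 3 the list held 0 called genes, and without both arrays numbered 4 it also held 0. Leaving out wild type 2, wild type 4, Nova2 KO 1 or Nova2 KO 4 gave 2 each. The replicate number of the titles as a block also gave 2 (permutation p = 0.0017). Of the 2 genes with a reported Nova-dependent 3-prime end, neither passed: the leading probe set of Slc8a1, the sodium-calcium exchanger, differed by 1.07 log2 (SE 0.15, adjusted p = 0.172) and that of the splicing regulator Celf2 by -0.52 log2 (SE 0.12, adjusted p = 0.553). The Celf2 difference was -0.30 log2 without Nova2 KO 4.

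Expression of the Nova-dependent exon genes went both ways, with 16 members above and 14 below 0, a median of 0.0063 log2 and a mean of 0.015 log2, although the direction given by camera was down. For changes in either direction the fry mixed adjusted p was 0.00288 over 23 lists. Map4 rose, and adjusted over the list alone Nova1 passed as well, with Kcnj6, a subunit of GIRK potassium channels (-0.47 log2). Among 24 measured splicing regulators, 18 were higher, with a median of 0.094 log2, which was 0.045 without wild type 4 and 0.14 without wild type 2. Adjusted over the list alone, 1 passed: Ptbp2 (0.50 log2, SE 0.11), which represses neuronal exons. The camera adjusted p of the splicing regulator list was 0.0224, and 0.538 with an estimated correlation.

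Genes of oligodendrocytes and myelin were the group with the lowest p. Of 13 measured genes, 12 were lower in Nova2 KO, with a median of -0.36 log2 (camera adjusted p = 4.87e-08, and 0.0514 with an estimated correlation; fry adjusted p = 0.0146). Mog fell over all genes, and adjusted over the list alone 6 fell: Mog, Mag (-0.64 log2, SE 0.14), Mobp (-0.58 log2, SE 0.16), Cnp (-0.37 log2, SE 0.11), Cldn11 (-0.50 log2, SE 0.17) and Mbp (-0.34 log2, SE 0.13). These encode structural proteins or enzymes of the myelin sheath. Parted after the values were seen, the mean of the 5 lineage genes (Olig1, Olig2, Sox10, Pdgfra and Gpr17) differed by -0.11 log2 (exact permutation p = 0.143, two-sided), and that of the other 8 genes by -0.48 log2 (exact permutation p = 0.0286). Because the parting followed the values, these p do not test the contrast between the 2 parts. Within the lineage genes, values ran from Gpr17 (-0.36 log2) to Sox10 (0.046 log2).

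Immediate early genes, which follow neuronal activity, had a median of -0.32 log2 over 9 measured genes (camera adjusted p = 0.000211, and 0.32 with an estimated correlation). None passed over all genes with limma, where 6 had an unadjusted p under 0.05. Adjusted over the list alone 3 fell: Arc (-0.55 log2, SE 0.12), Egr4 (-0.49 log2, SE 0.14) and Egr1 (-0.60 log2, SE 0.19). Presynaptic release genes had 13 of 18 members lower (median -0.12 log2, camera adjusted p = 0.00608, and 0.501 with an estimated correlation), with Syn1 at -0.25 and Rims1 at -0.29 log2. Of 18 genes of the glutamatergic postsynapse, 13 were lower (median -0.062 log2, camera adjusted p = 0.0188, and 0.538 with an estimated correlation). Without wild type 4 this median was -0.13 log2, and without Nova2 KO 4 it was 0.00083 log2. The scaffold Shank3 (-0.52 log2, SE 0.12) passed adjusted over the list alone, and Camk2a was at -0.35 log2, with Nova2 KO 1 apart from the other Nova2 KO arrays. GIRK channels and GABA-B receptors had a median of -0.12 log2 over 5 genes (camera adjusted p = 0.0258, and 0.501 with an estimated correlation), and Kcnj6 was the 1 member past the threshold over the list alone. The median was -0.21 log2 without wild type 4 and -0.077 log2 without wild type 1.

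Deep-layer neuron markers were higher in 11 of 12 measured genes, with a median of 0.17 log2 (camera adjusted p = 0.00592, and 0.32 with an estimated correlation). The median was 0.11 log2 without Nova2 KO 3. Foxp2 was at 0.33 log2, with Nova2 KO 3 apart from its group, and Fezf2 at 0.29 log2, and neither passed. All 5 measured cell cycle genes were higher (median 0.20 log2, camera adjusted p = 0.0258, and 0.32 with an estimated correlation), and Pcna (0.66 log2, SE 0.17) passed adjusted over the list alone. The cell cycle list lost its call in 5 of 13 other settings. Endothelial and pericyte markers were lower in 11 of 12 genes (median -0.12 log2, camera adjusted p = 0.00313, and 0.32 with an estimated correlation), with the transporter Slco1a4 at -0.31 log2. With an estimated correlation, none of these 9 lists had a camera adjusted p under 0.05. With fry, oligodendrocytes and myelin alone passed among the 9. The fry adjusted p of the others ran from 0.0775 (cell cycle and deep-layer neurons) to 0.499 (glutamatergic postsynapse). In the fry mixed test over 23 lists, adjusted p was 0.00187 for oligodendrocytes and myelin, 0.0102 for splicing regulators, 0.0108 for immediate early genes and for deep-layer neurons, and 0.0176 for endothelium. It was 0.113 for the cell cycle, 0.16 for presynaptic release, 0.242 for the glutamatergic postsynapse and 0.291 for GIRK channels and GABA-B receptors.

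The other lists did not pass with camera at the preset correlation. Upper-layer neuron markers had a median of 0.06 log2 over 10 genes (adjusted p = 0.51), with Mef2c at 0.37 log2. Interneuron markers had a median of 0.11 log2 over 13 genes (adjusted p = 0.153), with Dlx1 at 0.29 log2 and Npy at 0.30 log2, where wild type 4 stood apart. Reelin pathway genes had a median of 0.12 log2 over 10 genes (adjusted p = 0.183), and axon guidance genes -0.0049 log2 over 20 genes (adjusted p = 0.274). Inhibitory postsynapse genes had a median of 0.034 and a mean of -0.0032 log2 over 13 genes (adjusted p = 0.619), and p53 targets a median of -0.12 log2 over 6 (adjusted p = 0.274). Astrocyte markers had a median of -0.065 log2 over 12 genes (adjusted p = 0.152), with Slc1a2 at -0.23 log2 and wild type 4 apart, and microglial markers -0.055 log2 over 10 (adjusted p = 0.0883). Meningeal genes had a median of -0.071 log2 over 7 genes (adjusted p = 0.114). Leaving out 1 array moved several of these medians. Without wild type 4 the reelin pathway was at 0.043 log2, and without Nova2 KO 1 upper-layer markers were at 0.0078 log2. Without Nova2 KO 4, p53 targets were at -0.035, interneurons at 0.17 and meninges at -0.19 log2. Astrocytes were at -0.014 log2 without Nova2 KO 3 and at -0.12 log2 without Nova2 KO 4. The astrocyte gene Slc1a2 was at -0.13 log2 without Nova2 KO 3.

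Markers of neighbouring regions and of blood were read as a description of the dissection. Striatal genes had a median of -0.032 log2 over 6 (adjusted p = 0.451), and adjusted over the list alone Tac1 was higher (0.51 log2, SE 0.14) and Penk lower (-0.47 log2, SE 0.12). Thalamic genes had a median of -0.032 and a mean of 0.017 log2 over 5 (adjusted p = 0.856), with Prkcd (0.27 log2, SE 0.088) past the threshold over the list alone. Choroid plexus, hippocampus and blood each had 2 measured genes and were not tested as lists: Ttr was at 0.078 and Kl at -0.07 log2, Wfs1 at -0.45 and Grik4 at -0.23 log2, and Alas2 at -0.72 and Slc4a1 at -0.38 log2. Adjusted over the list alone, Wfs1, Grik4, Alas2 and Slc4a1 passed, and none did so over all genes. Single arrays stood apart for Grik4 (Nova2 KO 4) and for Slc4a1 (wild type 4 and Nova2 KO 2). Slc4a1 was at -0.25 log2 without wild type 4 and at -0.48 log2 without Nova2 KO 2. Sex-linked genes had 3 measured members, which did not differ between the groups beyond the spread (Xist 0.22 log2, SE 1.64).

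**Figure D4:**
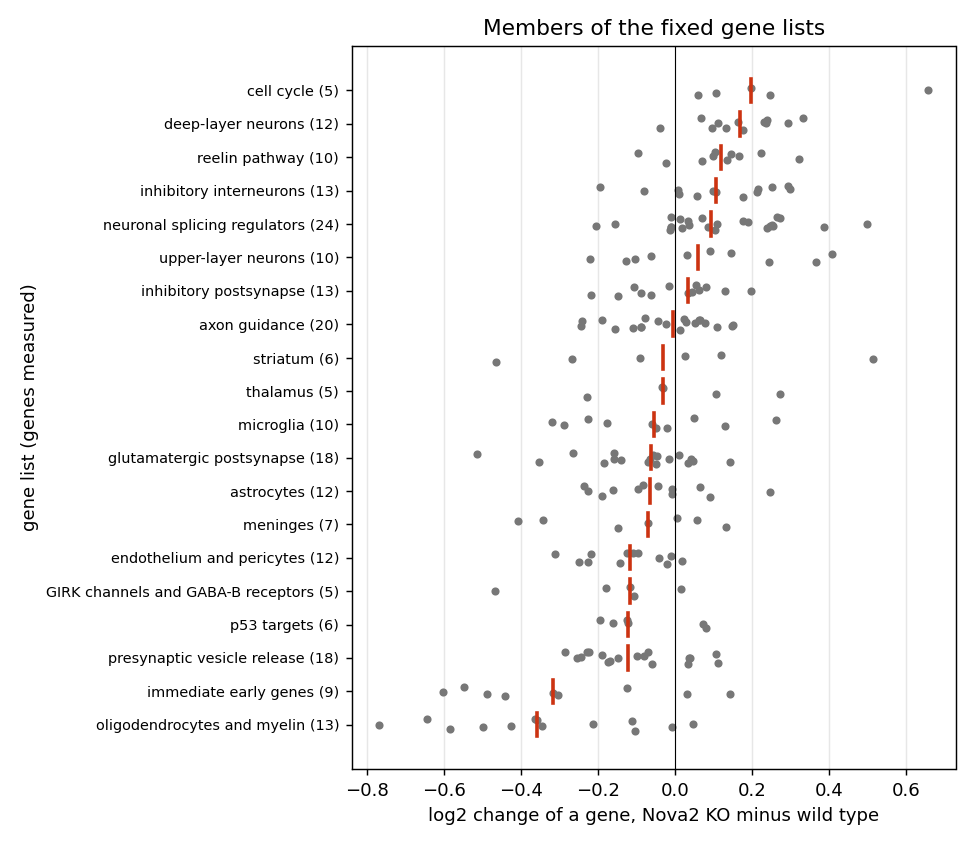
Log2 change of each measured gene, Nova2 KO minus wild type (x axis, n = 4 per group), in the 20 tested lists (y axis, with the number of genes measured), where each grey point is 1 gene and the red bar is the median of the list. Medians ran from -0.36 log2 for oligodendrocytes and myelin to 0.20 log2 for the cell cycle.

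Genes near Nova2 on chromosome 7 were compared with the rest, since a targeted locus can carry alleles of another strain. At the gene level 1 of 157 genes within 10 Mb of Nova2 passed (Zfp110), against 24 of 11835 elsewhere (Fisher's exact p = 0.281, two-sided). In exon usage 0 of 148 such genes passed, against 18 of 11039 elsewhere (limma with Simes, Fisher's exact p = 1). A list of 60 close neighbours had 41 measured genes with a median of -0.037 log2, of which 17 were higher and 24 lower, and adjusted over the list alone the DNA repair helicase Ercc2 was lower (-0.90 log2, SE 0.20). For changes in either direction this list had the lowest p of all 23 lists (fry mixed test, adjusted p = 0.000193 over the 23), and its camera adjusted p over the 23 was 0.0331, and 0.538 with an estimated correlation. In tests added after the values were seen, 10 of the 41 neighbours had an unadjusted p under 0.05 (24.4%, against 12.6% in matched random genes, one-sided permutation p = 0.026), while their mean absolute t was 1.26 against 1.13 (permutation p = 0.187). Within 10 Mb the shares were 14.6% against 12.01% at the gene level (permutation p = 0.179) and 10.8% against 8.39% in exon usage (permutation p = 0.176). With the array median as a covariate 4 genes near Nova2 passed (Fisher's exact p = 0.00538), and without any 1 of the 8 arrays, such as wild type 1, 0 passed.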

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

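Within a group of 4 arrays, an array was picked out when its gap to the nearest of the others exceeded 0.829 of the range of the group, the critical value of Dixon's test. Of 228 groups examined, over named genes, probe sets and array medians, 13 had such an array. Chance gives about 1 in 20, here 11.4. Wild type 4 was the array apart in 6 of the 13 and Nova2 KO 4 in 1, and these 2 arrays also had the lowest medians. No explanation was tested for these values.

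In wild type, array 4 stood apart for Atg4a (6.27 against 7.16 to 7.19 log2, ratio of gap to range 0.97), Itpr1 (8.999 against 9.38 to 9.42 log2, ratio 0.904), Npy (10.65 against 10.20 to 10.22 log2, ratio 0.966), Slc1a2 (11.53 against 11.72 to 11.75 log2, ratio 0.85) and Slc4a1 (7.54 against 7.09 to 7.15 log2, ratio 0.862). It also stood apart for the splicing index of Kcnma1 probe set 5193338 (-0.78 against -0.91 to -0.90 log2, ratio 0.888). Wild type array 2 stood apart for Map4 (10.04 against 10.13 to 10.15 log2, ratio 0.842) and Slc4a3 (9.87 against 9.74 to 9.75 log2, ratio 0.932). Among the Nova2 KO arrays, array 1 stood apart for Camk2a (11.56 against 11.32 to 11.33 log2, ratio 0.955), array 2 for Slc4a1 (7.16 against 6.72 to 6.76 log2, ratio 0.914), array 3 for Foxp2 (8.33 against 8.05 to 8.09 log2, ratio 0.857) and array 4 for Grik4 (8.10 against 8.23 to 8.24 log2, ratio 0.904). Nova2 probe set 5489900 had array 3 apart in Nova2 KO (7.82 against 8.08 to 8.10 log2, ratio 0.925).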

How the results depend on the processing

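The array median as a covariate, the fit without both arrays numbered 4, and offsets 1 and 64 were chosen after the results were seen. The planned pseudocounts on linear values were not run because the table was on a log2 scale. Where a value moved, the cause was not tested, apart from the lower number of arrays in fits that left some out. Probe set 5294108 of Nova2 kept its direction and its side of the threshold in all 17 alternatives.

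The count of single probe sets was 20 (10 higher, 10 lower). It was 86 with quantile normalization (29 higher, 57 lower), 85 with median centring (32 higher, 53 lower), 6 without a filter, 88 with the filter at the 50th percentile, 165 with trend and robust eBayes, 13 with the Xist covariate, 184 with the array median, 2 without both arrays numbered 4, and 6 and 90 with offsets 1 and 64. The count of 25 genes became 13 with median centring, 54 with the array median and 12 without both arrays numbered 4. The 26 exon usage probe sets became 15 without a filter, 16 with the Xist covariate, 43 with the mean over probe sets, 506 with diffSplice and 2 without both arrays numbered 4. The 18 genes called for exon usage became 11, 425 and 0 without a filter, with diffSplice and without both arrays numbered 4. The 6 genes on the Nova-dependent exon list became 14 with diffSplice and 0 without both arrays numbered 4.

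Leaving out each array in turn gave 0 to 9 single probe sets, 6 to 16 genes, 10 to 16 exon usage probe sets, 0 to 13 genes called for exon usage and 0 to 5 genes on the Nova-dependent exon list. For the genes near Nova2, the count of 1 became 0 with quantile normalization, median centring, the filter at the 50th percentile, trend and robust eBayes, the Xist covariate, without both arrays numbered 4, with offset 64 and in each fit with 1 array left out (0 to 0). It was 4 with the array median (Fisher's exact p = 0.00538), and in exon usage it was 10 with diffSplice (Fisher's exact p = 0.0771).

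Of the 9 lists past the threshold with camera, the cell cycle lost its call with median centring (adjusted p = 0.0554), without a filter (0.0587), with the filter at the 50th percentile (0.0973) and with the mean over probe sets (0.125). Splicing regulators lost it without a filter (0.0754), and GIRK channels and GABA-B receptors with the filter at the 50th percentile (0.121). With 1 array left out, the cell cycle, splicing regulators, GIRK channels and the glutamatergic postsynapse each lost the call in 3 of 8 fits and the presynaptic list in 1. Microglia gained a call with the filter at the 50th percentile (0.0469) and in 2 fits with 1 array left out, meninges in 2 and astrocytes in 1, and interneurons without both arrays numbered 4 (0.0429).

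Among named genes, 9 lost their call with median centring and 8 of these without both arrays numbered 4 (Zfp110, Cep112, Map4, Mog, Mal, Sla, Lynx1 and Rasgrf1, not Snrpe). These kept their direction.

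Among named exon usage probe sets, those of Tln2, Gria3, Cyp2d9, Abi3bp, Map7d2, Nrcam and Cltc lost their call without a filter. With the Xist covariate Tln2, Gria3, Cyp2d9, Abi3bp, Map7d2 and Cltc lost it, and with offset 1 Tln2, Gria3 and Abi3bp. Tln2 also lost it with quantile normalization (-2.92 log2, adjusted p = 0.0891), Gria3, Cltc and Kcnma1 with trend and robust eBayes, Cyp2d9 with the mean over probe sets and Abi3bp with the array median. Without both arrays numbered 4, Ank3 and Gphn alone kept it.

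The replicate numbers of the titles were used as a block in a paired fit. Deviations of same-numbered arrays correlated at 0.131, 0.411, 0.0818 and 0.521, and since 1 of the 4 lay under 0.1 the numbers were not taken to pair the mice. As a hint from the data, not the design, 7 of the 8 arrays correlated best with their own number, and wild type 3 correlated best with Nova2 KO 2. With the replicate block, 7 single probe sets, 80 genes (25 of them shared with the 25), 4 exon usage probe sets, 3 genes by Simes and 2 Nova-dependent exon genes (permutation p = 0.0017) passed, and 4 genes near Nova2 (Fisher's exact p = 0.0207). With the block the cell cycle list had an adjusted p of 0.0606, and of the named exon usage probe sets Chl1, Ank3, Adam11 and Gphn were called.

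Direction turned for a few values near 0. The camera direction of the thalamus list turned with median centring (median -0.028 log2), with the block (-0.032 log2) and without wild type 2 or 3 (range over arrays left out -0.072 to 0.050 log2). Upper-layer markers had a median of -0.023 log2 with the mean over probe sets. Over single arrays left out, the lists turned within -0.13 to 0.018 log2 for striatum, -0.093 to 0.069 log2 for the inhibitory postsynapse and -0.081 to 0.066 log2 for axon guidance. The median, though not the camera direction, crossed 0 for the glutamatergic postsynapse (-0.13 to 0.00083 log2), microglia (-0.12 to 0.016 log2) and meninges (-0.19 to 0.0034 log2). The Nova2 gene value was 0.053 log2 without both arrays numbered 4 and -0.10 to 0.026 log2 over single arrays left out, and Slc4a1 was at 0.058 log2 with the filter at the 50th percentile.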

Other observations

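The tests of the signal floor, of array-wide quality, of linked alleles by the share of genes near Nova2, of the oligodendrocyte lineage and of Scn9a, and the counts of exon usage by list, were chosen after the results they bear on were seen. The lists of early and late neuronal genes were written after the gene-level results and before their own test.

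Genes of growing neurons were higher in Nova2 KO as a group, while the lower values of genes of mature neurons did not pass with an estimated correlation. Any of the 25 called genes were left out of the early and late lists before testing. Of the 16 measured early postnatal neuronal genes that remained, 15 were higher (median 0.22 log2, camera p = 5.25e-06, and p = 0.00275 with an estimated correlation). Examples were the axon growth genes Dpysl3 (0.45 log2, SE 0.096) and Dpysl5 (0.35 log2, SE 0.091) and the tubulin regulator Stmn1 (0.30 log2, SE 0.099). Of 21 late postnatal neuronal genes, 15 were lower (median -0.18 log2, camera p = 0.000127, and p = 0.13 with an estimated correlation). Among these, the synaptic pentraxin Nptx1 was at -0.47 log2 (SE 0.13), the dendritic adhesion gene Icam5 at -0.42 log2 (SE 0.12) and the neurofilament gene Nefl at -0.40 log2 (SE 0.14). Because of that removal, none of these genes could be past the threshold over all genes with limma, where 1389 genes had an unadjusted p under 0.05.

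Exon usage calls were also counted in the 20 expression lists. Grin1 was called in the glutamatergic postsynapse, where Gria3 also had a called probe set (permutation p = 0.184, adjusted p = 1 over the 20 lists), and Gphn in the inhibitory postsynapse (permutation p = 0.0424, adjusted p = 0.848 over the 20 lists). The other 18 lists held 0 genes called by limma with Simes, although 936 genes had an unadjusted p under 0.05.

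Splits of the 8 arrays into 4 and 4 numbered 35. At the gene level 1 of the 35 splits, the real one, gave as many genes as the real count of 25, and the highest other split gave 3. In exon usage 1 of 35 gave as many probe sets as the real 26 (highest other 4). For genes called in exon usage, 1 of 35 gave as many as the real 18 (highest other 2). First place is the most that 35 splits can show. Taken 1 by 1, these counts passed the 5% level, without adjustment for the several counts tested. For single probe sets 2 of 35 splits gave 20 or more, so chance cannot be excluded at that level. The other split was the one that set the arrays with high Xist (wild type 1 and 4, Nova2 KO 2 and 4) against the rest, with 55 probe sets, which points to the sex of the mice as a structure in these samples. The highest of the remaining splits gave 17. It set the arrays numbered 1 and 2 of both groups against those numbered 3 and 4, and was also the highest other split in exon usage. With the Xist covariate 13 probe sets passed.

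Exon usage changes in Nova2 KO may reflect the loss of Nova2-dependent splicing. The signal floor was examined with offset 64, which damps dim signal, and 26 of 26 probe sets stayed called. Calls as a whole rose to 32 with this offset, so staying called cannot decide the question. In their dimmer group, 12 of the 26 lay above the 50th percentile, which argues against the floor for these 12. In the same group 8 of the 26 lay under the 25th percentile (Grik2 at 5.57 log2 in wild type, Tln2 at 5.97 log2 in Nova2 KO), where the floor stays open. Array-wide quality was examined with the array median as a covariate, and 23 of 26 probe sets stayed called. Array medians ran over nearly the same range in both groups (7.02 to 7.37 log2 in wild type, 7.06 to 7.37 log2 in Nova2 KO). The covariate could thus hardly move a group difference, and this test cannot decide on array-wide quality. Linked alleles as the whole cause are argued against by the 0% of genes with a called probe set within 10 Mb of Nova2. The Nova-dependent exon list held 6 called genes where matched random lists held at most 5, as the loss of Nova2 would give, with the reservation that part of that list came from brains without Nova2. With the replicate number of the titles as a block, 4 of the 26 probe sets stayed called. Without both arrays numbered 4, only 2 probe sets stayed called with fewer arrays. The 21 named called probe sets kept 90.5% to 110% of their change (Chl1 2.86 against 2.89 log2). They were chosen as called on all 8 arrays, where their groups did not overlap, so their change could hardly move. Array-wide quality and alleles elsewhere in the genome stay open.

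Lower myelin genes in Nova2 KO could come from later maturation of the cortex, from fewer oligodendrocytes or from array quality. An equal loss over the whole lineage is argued against by the mean of 8 myelin genes minus that of 5 lineage genes, which differed by -0.374 log2, though the list was parted after its values were seen, and Gpr17 (-0.36 log2) leaves a loss of committed cells open. Array quality stays open. The median was -0.354 log2 with the array median as a covariate, but array medians ran over nearly the same range in both groups. That covariate could thus hardly move a group difference. Later maturation is in line with the score of early minus late neuronal genes, which was 0.373 log2 higher in Nova2 KO (1.16 ± 0.12 in wild type and 1.53 ± 0.14 in Nova2 KO, SD, n = 4, exact permutation p = 0.0286, two-sided), although the late genes alone did not pass (-0.16 log2, exact permutation p = 0.0857; early genes 0.22 log2, p = 0.0286). The early and late lists were written after the gene-level results, with called genes left out, so this score is not an independent test. A change within oligodendrocytes that does not follow from age stays open, as does a difference in dissection, which was not tested.

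Scn9a rose at 23 of its 27 probe sets and not at the 4 brightest. Saturation stays open: 3.15% of all probe sets on the arrays were brighter than the brightest of Scn9a, but the ceiling of each probe set is its own and was not measured. Another transcript that reaches the bright probe sets may hold their signal steady, and the mean change of these 4, -0.15 log2, cannot tell this apart from probes that hybridise to unrelated RNA. The positions of the probe sets, which were not analysed here, would be needed. No biological explanation was tested for the rise itself.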
